A study of Mus musculus with 2 samples.

How the data were processed

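Trimethylation of lysine 36 of histone H3 (H3K36me3) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the midbrain of mouse embryos at day 14.5. Per the labels, there were 2 biological replicates, made from pools of 24 and 34 embryos of both sexes, with libraries of 300 to 500 bp fragments. They form 1 group, so no comparison between conditions was possible.

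The authors deposited 4 peak lists on the mouse build mm10, per the file headers. These are a list for each replicate, a list called on both replicates together (pooled), and a list of replicated peaks, which is derived from the other 3. All 113509 replicated peaks were peaks of the pooled list. Of these, 94.8% overlapped a peak of replicate 1 and 85.3% a peak of replicate 2, and 90.0% and 73.5% were at least 50% covered by those peaks, so a replicated peak is not always a peak of both replicates. Of the 59587 pooled peaks left out of the list, 10 were at least 50% covered by the peaks of each replicate. Each deposited peak has a signal value, taken as a fold enrichment (ratio) over control, and its p-value and q-value as −log10. These are the authors' values for that peak, and they were used to describe, rank or filter peaks within a list. The peak caller, aligner and their versions are not given in the sources used here. The lowest −log10 p in the deposited lists was 2.03 to 2.06, and 2.32% of replicated peaks, 10.8% of replicate 1 peaks and 19.7% of replicate 2 peaks had a −log10 q under 2. Per the file headers, the list of replicate 1 and the pooled list name 1 input file more than the list of replicate 2, so the control used in the calls may differ between replicates. The lists hold no read counts, so the depth of each library is unknown, and intervals given for shares of genes or peaks cover counting error only.

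Genes were taken from GENCODE mouse release M21, whose assembly is that of mm10, and all peaks ended within its chromosomes. The gene comparisons used peaks on chromosomes 1 to 19, X and Y. The covered share of a gene is the percent of base pairs between its annotated start and end that lie in peaks. A protein-coding gene of at least 1 kb with a covered share of at least 10% in the replicated list is called marked. The same definition was applied to each replicate's own list. A peak inside overlapping genes counts for each of them, and without strand it cannot be assigned to 1 of them, so overlapping genes are uncertain. Of the 7737 marked genes, 4444 overlapped another gene.

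The overlap of the replicates and the share of peak base pairs in gene bodies were set against 1000 circular shifts of a list within each chromosome, leaving out the first 3 Mb of each. The smallest p these shifts can give is 0.000999 one-sided and 0.002 two-sided. Position along the gene was measured in 10 equal bins in genes of at least 10 kb with a replicated peak. Promoters were the 500 bp either side of the transcription start site (TSS). The 29 gene lists, 24 given by symbol and 5 gene families given by name, were set against 10000 random lists of the same size, matched on gene length in 20 bins (two-sided permutation test), with Benjamini-Hochberg adjustment over the 29 lists. One listed symbol, Ahsp, had no match in the annotation. The X chromosome was compared with the autosomes by a two-sided Fisher's exact test. Exact Clopper-Pearson intervals are at 95%. Where a count was 0, the upper limit given is 3 counts divided by the number of genes, which is a little below the Clopper-Pearson bound. Genes share chromatin domains and are not independent replicates, so these tests describe how the mark is placed within the 2 replicates.

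The lists, tests, thresholds and the rule for named genes were set before the data were examined, except where stated. The rule names members of the gene lists, the 10 protein-coding genes of at least 10 kb with the highest covered share, the 10 with the largest difference between replicates, and the 5 replicated peaks with the highest signal value at least 5 kb from any gene. The alternatives were each replicate's own list in turn, the pooled list, peaks with a −log10 q of at least 2, marked at 5% or 25% of the gene body, genes of at least 20 kb, genes overlapping no other gene, all annotated genes, no minimum gene length, promoters of 1000 bp either side, a 50% overlap, an equal number of strongest peaks, peaks within 1 kb joined, Fisher's exact test for the gene lists, receptors left out of the X comparison, and −log10 p in place of the signal value. Weighting each gene equally in the exon comparison and leaving receptors out of the background of the gene lists were chosen after seeing the data.

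Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9. The interval arithmetic was checked against base-by-base counting, with 0 differences in 5000 queries. On simulated marking of the 21221 genes at the observed rates for their lengths, the test called 2 of 100 random lists of 20 genes at an unadjusted 0.05. It called 100 of 100 such lists with 80% of genes marked, 50 of 100 with 60% marked and 100 of 100 with 0% marked. With lists of 10 genes it called 26 of 100 at 60% marked and 96 of 100 at 0% marked. Each gene was marked independently, lists were drawn at random, and fewer random lists were used than in the main test. These rates therefore do not carry over to lists of neighbouring genes, such as Hox. Of 20 shifted peak lists, 1 was called enriched or depleted in genes. These lists held a part of the replicated peaks and were set against fewer shifts. They are made in the way the test assumes, so this checks the calculation only.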

Results

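H3K36me3, a histone mark laid down over transcribed gene bodies, was profiled by ChIP-seq in the midbrain of mouse embryos at day 14.5. The midbrain at this stage holds dividing progenitors and newly made neurons. Replicate 1 was a pool of 24 embryos and replicate 2 a pool of 34, both of mixed sex, so the group has n = 2. In replicate 1, 179945 peaks covered 108.6 Mb, or 3.99% of the chromosomes. In replicate 2, 156335 peaks covered 83.9 Mb, or 3.08%. The authors' replicated list held 113509 peaks over 106.9 Mb, with a median width of 579 bp. Unless stated otherwise, the values below are covered shares by replicated peaks on build mm10. A second set of values, as mean ± SD with n = 2, comes from the replicates' own lists.

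The replicates marked largely overlapping sets of genes. A total of 7071 protein-coding genes were marked in both, 948 in replicate 1 alone and 85 in replicate 2 alone. Across the 21221 genes compared, which are not independent replicates, the covered shares of the 2 replicates had a Pearson r of 0.981 and a Spearman rho of 0.966. At the level of base pairs, the intersection of the 2 lists made up 0.541 of their union (Jaccard index), against 0.0211 ± 0.0017 (SD over 1000 circular shifts), with a permutation p of 0.000999 (one-sided), the smallest these shifts can give. Overlap with the other replicate was found for 63.7% of replicate 1 peaks and 84.2% of replicate 2 peaks. Replicate 1 covered 1.29 times as many base pairs. The 10 genes of at least 10 kb with the largest difference between replicates were all higher in replicate 1. They were Lrrc61, Ccnf, Trmo, Eef1akmt2, Zfp653, Nlgn3, Ap4b1, Zfp956, Haus5 and Nit2. This direction was the common one, as 5697 of the 5877 marked genes of at least 10 kb had more cover in replicate 1. Lrrc61 led with 41.8% covered in replicate 1 and 12.2% in replicate 2, followed by the cyclin gene Ccnf with 61.5% and 32.3%.

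The mark lay almost entirely within genes. Protein-coding gene bodies take up 38.2% of the chromosomes and held 95.1% of the base pairs of replicated peaks. The share was 94.9% in replicate 1 and 95.3% in replicate 2. Circularly shifted peaks fell in gene bodies at 41.9% ± 1.08 (SD, 1000 shifts), so the observed share was 2.27 times higher (permutation p = 0.002, two-sided, the smallest these shifts can give). Of the 113504 replicated peaks on chromosomes, 212 (0.187%, exact 95% interval 0.162 to 0.214) lay at least 5 kb from any annotated gene. The 5 of these with the highest signal values lay at chromosome 7 28192539 to 28196016, chromosome 10 79051062 to 79052761, chromosome 5 104583021 to 104583678, chromosome 6 37972538 to 37973119 and chromosome 16 3756896 to 3758608. The first lay 5.24 kb from Dyrk1b, a kinase gene, and had a signal value of 7.08. The fifth lay 6.11 kb from Zfp263 and had a signal value of 5.83.

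The 10 genes of at least 10 kb with the highest covered share were Sf3a1, Rnf40, Kpnb1, Rbm5, Glyr1, Trrap, Sf3b3, Exosc10, Ddb1 and Kdm4a. Sf3a1 and Sf3b3 encode splicing factor subunits, and Rbm5 a further splicing regulator. Exosc10 is part of the RNA exosome, Kpnb1 is a nuclear import receptor, Rnf40 is part of the ubiquitin ligase for histone H2B, and Kdm4a is a demethylase acting on H3K36me3 and H3K9me3. Sf3a1 (chromosome 11, 4160350 to 4182541) was covered over 94.0% of its 22.2 kb (88.8% ± 4.59, SD, n = 2). Kdm4a (chromosome 4, 118136957 to 118180043) was covered over 91.2% of its 43.1 kb (88.5% ± 4.80, SD, n = 2). Sf3a1 and Glyr1 overlapped no other annotated gene, while the other 8 did.

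**Figure D1:**
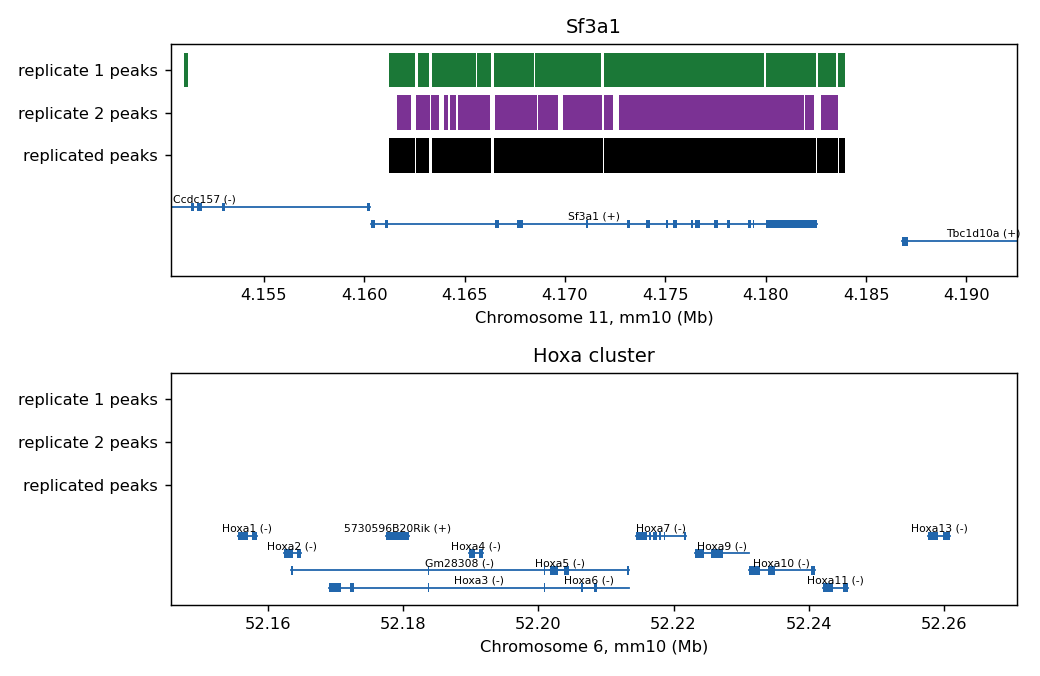
Peaks along Sf3a1 and along the Hoxa cluster, drawn to scale against mm10 position in Mb. Coloured bars are peaks of replicate 1 (green), replicate 2 (purple) and the replicated list (black), and blue lines and boxes are genes and exons with their strand. Replicated peaks fill 94.0% of Sf3a1 from downstream of its TSS past its annotated end, and none of these 3 lists has a peak in the Hoxa cluster.

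Cover rose along genes from the TSS to the transcription end site (TES). In the 8217 genes of at least 10 kb with a replicated peak, mean cover was 4.18% in the first of 10 bins and 48.1% in the last. By the replicates' own lists, it rose from 4.30% to 43.5% in the 8916 such genes with a replicate 1 peak. In the 8494 with a replicate 2 peak it rose from 3.01% to 37.4%. Cover by replicated peaks was higher on the 3′ side of the gene's midpoint in 7000 of the 8217 genes (85.2%, exact 95% interval 84.4 to 86.0). The means were 20.6% on the 5′ side and 42.5% on the 3′ side. Among the genes holding a peak of each replicate's own list, the share was 84.2% in replicate 1 and 84.6% in replicate 2.

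**Figure D2:**
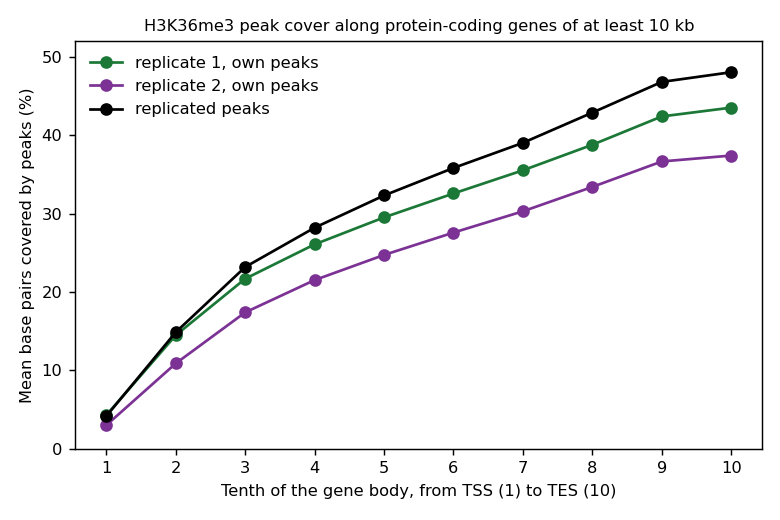
Mean percent of base pairs covered by peaks (vertical axis) in each of 10 equal bins of the gene body from TSS to TES (horizontal axis), for protein-coding genes of at least 10 kb holding a peak of the list drawn. Each list rises from the first to the last bin, the replicated peaks (black) from 4.18% to 48.1%, replicate 1 (green) from 4.30% to 43.5% and replicate 2 (purple) from 3.01% to 37.4%.

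Promoters of marked genes were nearly free of the mark. In the 5877 marked genes of at least 10 kb, peaks covered 1.08% of the base pairs within 500 bp of the TSS and 43.5% of the rest of the gene body. The body had the higher cover in 5808 of them. Marked genes are chosen for cover of at least 10% of the gene body, so this count is partly set by that choice. Only the outermost annotated start of each gene was used, so promoters inside a gene count as body. In the genes marked by each replicate's own list, promoter cover was 1.01% in replicate 1 and 0.953% in replicate 2. Body cover was 41.5% and 37.0%.

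Within marked genes, exons were covered more than introns. Peaks covered 60.4% of exonic and 32.9% of intronic base pairs, a ratio of 1.84 (1.82 in replicate 1 and 1.85 in replicate 2). Exon cover was the higher in 6173 of 7616 marked genes with introns, and lower in 1417. With each gene weighted equally, a choice made after seeing the data, mean exon and intron cover were 59.6% and 39.2%. With first and last exons left out, 69.6% of exonic base pairs were covered (66.1% in replicate 1 and 61.2% in replicate 2). Exons and introns were not matched for position along the gene, where cover rose, so position was not separated.

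By the 10% definition, 7737 of 21221 protein-coding genes (36.5%, exact 95% interval 35.8 to 37.1) were marked. The number was 8019 in replicate 1 and 7156 in replicate 2. Another 10957 genes held no replicated peak. The median covered share of marked genes was 41.7%, against 40.5% by the own peaks of replicate 1 and 31.9% by those of replicate 2. Replicated peaks are peaks of the pooled list, so their cover can exceed that of both replicates. In Sf3a1, for example, it was 94.0% against 92.1% and 85.6%. With genes that overlap another gene left out, 3293 of 11180 (29.5%) were marked.

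Of the 29 gene lists, 6 held more marked genes than length-matched random lists and 11 held fewer (two-sided permutation test, Benjamini-Hochberg adjusted over 29 lists). Genes for basic cell functions were the most often marked. Of the 78 ribosomal protein genes, 67 were marked (85.9%) against 24.1% expected from their short lengths (adjusted p = 0.00116, permutation, the smallest these random lists gave). By the mean of the replicates' own lists, the most covered of them were Rps3, with 78.3% ± 0.956 (SD, n = 2), and Rpl26, with 76.9% ± 0.392 (SD, n = 2). Replicated peaks covered 81.3% and 77.8% of these genes, and 84.7% of Rps15a. Of 20 housekeeping genes, 18 were marked (90.0%, expected 39.3%, adjusted p = 0.00116, permutation). The translation elongation factor gene Eef2 was 77.8% covered, the chaperone gene Hsp90ab1 72.1% and the actin gene Actb 65.4%. The 2 unmarked members were Hprt, on the X chromosome, with 2.53% and the lysosomal enzyme gene Gusb with 2.09%. Of 21 genes that write, erase or read H3K36 methylation, 17 were marked (81.0%, expected 41.0%, adjusted p = 0.00249, permutation). The methyltransferase gene Setd2, which makes H3K36me3, was 46.0% covered, Nsd1 62.2%, and the reader genes Brd1 and Psip1 81.1% and 79.1%. Phf19, a Polycomb-associated reader gene, held no peak. This last call was lost when genes that overlap another gene were left out (adjusted p = 0.423, permutation), which leaves 4 of the 21 genes, 3 of them marked (75%, expected 35.2%).

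Genes shared by neurons were marked more often than matched genes, with 17 of 25 (68.0%, expected 29.1%, adjusted p = 0.00193, permutation). The kinesin gene Kif5a was 59.8% covered (55.0% ± 4.67, SD, n = 2), Crmp1 54.7%, the RNA-binding protein gene Elavl3 50.1%, the stathmin gene Stmn1 46.7% and the neuronal tubulin gene Tubb3 46.1%. The lowest were the RNA-binding protein gene Rbfox3, a marker of mature neurons, with 0.0837%, and the synaptic adhesion gene Nrxn1 with 0.280%. Of 24 cell cycle genes, 17 were marked (70.8%, expected 43.8%, adjusted p = 0.0286, permutation). The ribonucleotide reductase gene Rrm1 was 71.7% covered, and the replication helicase genes Mcm4 and Mcm7 67.7% and 61.4%, while the cyclin gene Ccnb1 held no peak. The cell cycle call was lost with the list of replicate 2 alone (15 of 24, adjusted p = 0.0818, permutation), with a −log10 q of at least 2 (0.0590) and when 25% of the gene body had to be covered (0.188).

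Zinc finger genes named Zfp, many of which encode KRAB repressors of repeats, formed the largest family above expectation. Of 365, 242 were marked (66.3%, expected 42.0%, adjusted p = 0.00116, permutation), with 246 in replicate 1 and 234 in replicate 2. Zfp869 was 98.8% covered, Zfp335 89.2% and Zfp606 87.2%. The 5 replicated peaks with the highest signal values all lay in genes of this family. They were in Zfp810 (chromosome 9, 22277979 to 22281160, signal value 13.6), Zfp157 (chromosome 5, 138454309 to 138459417, signal value 13.5), Zfp329 (chromosome 7, 12809143 to 12811716, signal value 12.7) and, with 2 peaks, in Zfp68 (chromosome 5, 138610322 to 138612260 and 138604862 to 138608822, signal values 13.3 and 12.6). The last exon took up 98.1% of the peak in Zfp329, 69.3% of that in Zfp157 and 40.9% of that in Zfp810. Of the 2 Zfp68 peaks, the second lay 74.7% in the last exon, while the first lay 11.2% in exons, with the largest part, 6.55%, in exon 4 of 6.

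Genes of midbrain identity were marked less often than matched genes. Of 27 midbrain and isthmus patterning genes, 4 were marked (14.8%, expected 35.3%, adjusted p = 0.0484, permutation). These were the homeobox genes Lhx1 (23.4%), En2 (21.7%) and Otx2 (16.1%) and the FGF antagonist gene Spry2 (14.8%). Replicate 2's own list marked 2 of the 27, with 8.71% of Otx2 and 6.79% of Spry2 covered. Replicate 1's marked 4, with Sall1 (10.1%) and without Spry2 (9.93%), so Spry2 was marked in neither replicate's own list. In 17 of the 27 no replicated peak was found, including Wnt1, Pax2, Lmx1a, Lmx1b and Foxa2. Of 14 dopaminergic neuron genes, 1 was marked (7.14%, expected 36.7%, adjusted p = 0.0437, permutation), and it was Otx2, which both lists hold. Replicate 2's own list marked 0 of the 14. Th, Ddc, Slc6a3, Nr4a2 and Pitx3, which make or specify the dopamine phenotype, held no replicated peak. Both calls lay close to the threshold and passed it with neither a −log10 q of at least 2 (0.0540 and 0.0501) nor genes overlapping no other gene (0.502 and 0.220). The samples mix the cells of the midbrain, so a gene without a peak, such as Th, may still carry the mark in some cells. This limit holds for the lists below too.

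Lists of other tissues and cell types were also low. No gene was marked among 39 Hox genes, 16 forebrain transcription factors, 13 genes of meninges and mesenchyme, 15 liver genes, 14 muscle genes and 12 germline genes. Their expected shares were 28.9%, 34.2%, 40.5%, 36.5%, 30.8% and 43.6%, and their adjusted p-values (permutation) were 0.00116, 0.00507, 0.00527, 0.00527, 0.0242 and 0.00527. A count of 0 allows a share of up to 7.69% of the Hox genes and 18.8% to 25% of the other 5 lists, for counting error only. Among 1302 olfactory and vomeronasal receptor genes 0 were marked, which allows a share of up to 0.230% (expected 32.5%, adjusted p = 0.00116, permutation). The highest covered among these were the forebrain genes Lhx2 with 5.98% and Bcl11b with 3.84%. Of 15 microglia and macrophage genes 1 was marked, Cx3cr1 with 16.8% (adjusted p = 0.0484, permutation), and the next, Csf1r, had 9.54%. Of 14 endothelium and pericyte genes 1 was marked, the glucose transporter gene Slc2a1 with 19.9% (adjusted p = 0.0286, permutation). Cx3cr1, annotated over 168 kb, and Slc2a1 both overlap another gene, so their cover cannot be assigned to them alone. Of these 9 lists, only the receptor list kept its call when genes that overlap another gene were left out, which removes 146 of its 1302 members and 23 of the 39 Hox genes. The microglia call was also lost with replicate 2's list (0.0754), the pooled list (0.127), a −log10 q of at least 2 (0.0540) and a 5% definition (0.0921), the endothelium call with replicate 2's list (0.05002) and the muscle call at a 25% definition (0.0689).

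The remaining 12 lists did not pass the test. Among GABAergic genes 4 of 13 were marked, namely the GABA transporter gene Slc6a1 (36.5%), Lhx5 (21.6%) and the GABA-synthesising enzyme genes Gad1 (21.4%) and Gad2 (20.4%). Gad1 was 25.6% covered in replicate 1 and 9.98% in replicate 2. Among glutamatergic genes 2 of 15 were marked, the vesicular transporter gene Slc17a6 (19.9%) and Ebf3 (13.5%). In radial glia and progenitors the count was 5 of 23, with Msi1 at 72.6%, the Notch ligand gene Dll1 at 60.6%, Vim at 43.2% and Notch1 at 32.8%, while Pax6, Hes1, Hes5 and Ascl1 held no peak. Imprinted genes gave 6 of 22, led by H13 (79.1%), Nnat (56.7%) and Igf2r (54.0%). Among axon guidance genes 2 of 21 were marked, Sema6a (24.9%) and Plxna2 (20.3%). The oligodendrocyte list gave 3 of 14, with the myelin enzyme gene Cnp at 75.5%, and the astrocyte list 2 of 10, with Acsl6 at 49.5% and Fgfr3 at 23.5%. Erythroid genes gave 1 of 11 (Tfrc, 63.9%), choroid plexus and ependyma 1 of 8 (Otx2), serotonergic and noradrenergic neurons 0 of 8, and immediate early genes 1 of 12 (Nr4a1, 12.7%). Replicate 2's own list marked 3 of the 12 immediate early genes, 1 of 15 glutamatergic, 1 of 14 oligodendrocyte, 1 of 10 astrocyte and 0 of 8 choroid plexus genes. Npas4, an immediate early gene, held no replicated peak, although the replicates' own lists covered 17.4% ± 2.57 (SD, n = 2) of it. Of 57 clustered protocadherin genes 21 were marked, but all 57 overlap another gene, so their counts are uncertain. Adjusted p-values (permutation) in these 12 lists ran from 0.0757 (serotonergic and noradrenergic) to 0.931 (GABAergic). Another setting brought 4 of them past the threshold. These were the 5% definition for serotonergic and noradrenergic neurons (0.0474), Fisher's exact test for axon guidance (0.0222), replicate 2's list for the oligodendrocyte lineage (0.0448) and the 25% definition for protocadherins (0.0206).

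**Figure D3:**
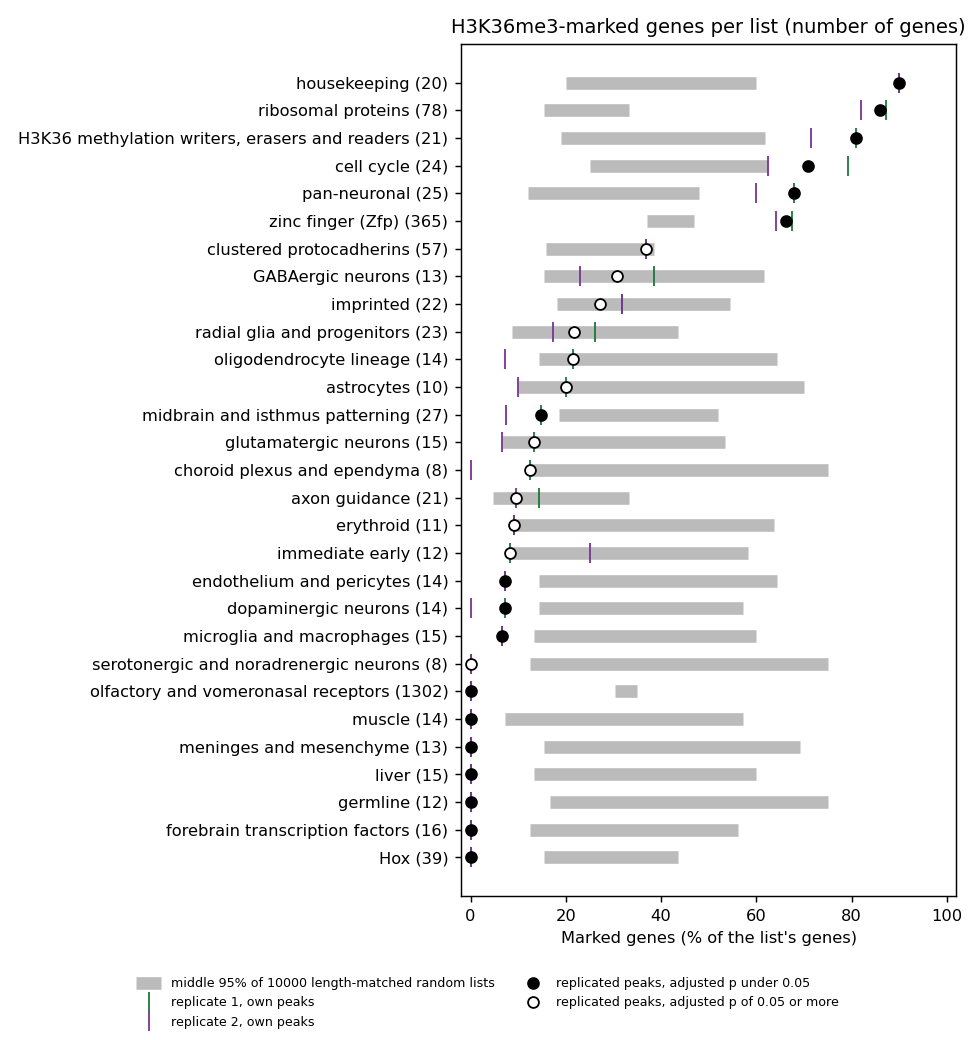
Percent of genes marked in each of the 29 lists (horizontal axis), with the number of genes in parentheses. Grey bars are the middle 95% of 10000 length-matched random lists, circles the replicated peaks (filled where the adjusted p is under 0.05) and ticks the own peaks of replicate 1 (green) and replicate 2 (purple). Housekeeping (90.0%) and ribosomal protein genes (85.9%) are at the top, and 8 lists are at 0%.

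Genes on the X chromosome were marked less often than autosomal genes. On X, 115 of 877 genes were marked (13.1%), against 7622 of 20181 on the autosomes (37.8%), an odds ratio of 0.249 (95% interval 0.204 to 0.303; Fisher's exact test, two-sided, p = 2.73e-57). The odds ratio was 0.274 with the list of replicate 1 and 0.212 with that of replicate 2. Among autosomes the share of marked genes ran from 29.4% on chromosome 14 to 48.0% on chromosome 8, above that of X in every case. X-linked members of the lists were marked in some cases, such as the RNA-binding protein gene Nono with 44.5%, the glycolytic gene Pgk1 with 19.0% and the doublecortin gene Dcx with 15.7%. None of the 163 Y-linked genes was marked. The pools held embryos of both sexes, so X in males and females was not separated.

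**Figure D4:**
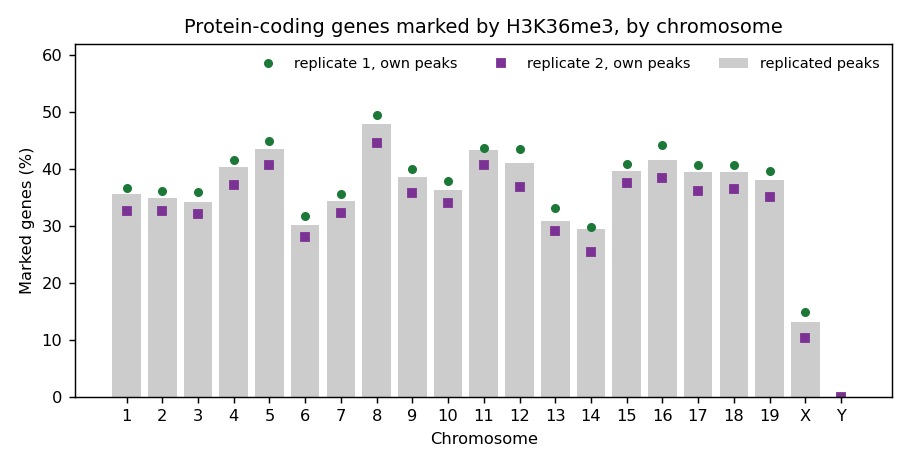
Percent of protein-coding genes of at least 1 kb marked on each chromosome (horizontal axis). Grey bars are the replicated peaks, and points the own peaks of replicate 1 (green) and replicate 2 (purple). The bar of X is at 13.1% and those of the autosomes lie between 29.4% and 48.0%.

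The authors' signal values, fold enrichments of each peak, had a median 1.09 times higher inside genes than outside. Among replicated peaks the median was 3.95 for the 108137 peaks in protein-coding gene bodies and 3.64 for the 5367 outside them. The medians were 3.66 and 3.37 in replicate 1, and 3.83 and 3.57 in replicate 2. Pooled peaks kept as replicated had a median of 3.95, against 2.85 for the 59573 not kept. These values describe peaks within each list, and no test was made.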

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

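The test of gene length was chosen after its result was seen, and the other tests were set before. With 2 samples in 1 group, neither outlying samples nor differences between groups were looked for. The design has no second group, so no biological explanation was tested for any pattern.

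Peaks were found in data that the comparisons leave out. The pooled list held 19 peaks on unplaced scaffolds, of which 5 were also replicated. They lay in the genes Vamp7 and Spry3 and in the unnamed genes CAAA01118383.1 and CAAA01147332.1, apart from 2 pooled peaks outside any gene. The strongest, with a signal value of 11.8, spanned positions 34016 to 36038 of the scaffold GL456216 in CAAA01118383.1. At least 5 kb from any annotated gene lay 212 replicated peaks, with a median signal value of 3.58 against 3.95 for all replicated peaks. Of the 3663 long intergenic non-coding RNA genes that overlap no other gene, 28 were marked (0.764%, exact 95% interval 0.509 to 1.10), and among those of at least 10 kb the most covered were 1700020I14Rik with 56.7% and D930016D06Rik with 41.5%.

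The first pattern is the low share of marked genes on X. It remained without genes named Gm or Rik and without olfactory and vomeronasal receptors. Of the genes left, 112 of 744 on X (15.1%) and 7382 of 17379 on the autosomes (42.5%) were marked. This gave an odds ratio of 0.240 (95% interval 0.196 to 0.294). Most receptors are autosomal, and leaving out receptors alone took X from 877 to 870 genes and the autosomes from 20181 to 18886. That moved the odds ratio from 0.249 to 0.225, away from 1. Other gene families of X were not left out, so gene content was tested only in part. Weaker enrichment along X as a whole remains open. For each gene with a replicated peak, the median signal value of a replicate's own peaks in it was taken. The median of these over X genes was 0.863 times that over autosomal genes in replicate 1 (95% bootstrap interval 0.857 to 0.893). In replicate 2 it was 0.869 times (0.869 to 0.902), with the lower bound equal to the ratio itself. The bootstrap resampled genes, which are not independent replicates. The signal value is taken as a ratio over control, so it does not show whether the 1 copy of X in males contributes. The lists cannot separate dosage, mappability and less transcription.

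The second pattern is that 12 of the 93 members of the patterning, forebrain, glutamatergic, progenitor and immediate early lists were marked; these hold many short transcription factor genes, but also other and longer genes. The patterning and forebrain lists differed from length-matched genes and the other 3 did not pass that test. Short length does not by itself prevent marking, as 85.9% of ribosomal protein genes were marked (exact 95% interval 76.2 to 92.7) against 36.5% of all genes. That share was already known, and it does not show what length does in these 5 lists. Length remains open for the glutamatergic, progenitor and immediate early lists, given the length-matched test (adjusted p = 0.335, 0.812 and 0.200, permutation). Few exons remain open as an explanation. The 12 marked genes had a median of 11 exons and the 81 unmarked ones 4 (permutation p = 0.00735, two-sided). The marked ones were also longer, with medians of 18.3 and 6.86 kb. Marked transcription factor genes were En2, Lhx1, Otx2, Nr4a1 and Ebf3, with 2, 6, 6, 10 and 17 exons. The other marked genes, Notch1, Prom1, Msi1, Dll1, Slc17a6, Vim and Spry2, had 36, 30, 16, 12, 12, 9 and 2. Exon number, length and kind of gene were therefore not separated. With olfactory and vomeronasal receptors left out, 65 of 774 single-exon genes were marked (8.40%, exact 95% interval 6.54 to 10.6). The share was 21.0% for length-matched genes with more exons.

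The third pattern is the larger cover of replicate 1. For the unshared peaks, repeat or copy number signal is argued against by where they lie. Of the base pairs of peaks found in replicate 1 alone, 92.1% were in gene bodies, and 92.0% of those in replicate 2 alone. None of 100 shifts exceeded 45.1%. Shared peaks were also wider in replicate 1, with a median width of 506 bp against 398 bp in replicate 2. That part of the larger cover was not in this test. Passing weaker sites of the same genes remains open, since 90.1% of the 948 genes marked in replicate 1 alone also held a replicate 2 peak. Peaks in 1 replicate alone were weaker than shared ones in both, with median signal values of 3.26 and 4.08 in replicate 1 and 3.32 and 3.90 in replicate 2. Likewise 80% of the 85 genes marked in replicate 2 alone held a replicate 1 peak, so these values do not show why replicate 1 covers more, nor separate depth, control and threshold.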

How the results depend on the processing

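The alternatives of equal weight per gene in the exon comparison and a gene list background without receptors, were chosen after seeing the data; the others were planned. No result past its threshold changed direction. The genic share, the 3′ bias and the X comparison kept direction and call in all settings run. Read depth is unknown and limits which weak sites passed; the cause of the changes below was not tested unless given.

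The Jaccard index of 0.541 was 0.530 with a −log10 q of at least 2, 0.548 with equal numbers of strongest peaks and 0.674 with peaks within 1 kb joined. In that order, and then with a 50% overlap, the shared percent was 59.6, 67.8, 57.0 and 50.1 for replicate 1 peaks and 85.8, 80.2, 77.7 and 75.3 for replicate 2 peaks. The exon to intron ratio was 1.81 with the pooled list, 1.62 in genes overlapping no other and 1.52 with equal weight per gene. The promoter to body ratio of 0.0247 was 0.0244 to 0.0258 with single replicates' lists and 0.0261 with 1000 bp promoters. The ratio of signal inside to outside genes, 1.09, was 1.07 to 1.09 with single replicates' lists and 1.18 with −log10 p.

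With genes overlapping no other gene, 3293 genes were marked and 1 list, not 11, stayed below. Fewer genes per list were tested in this setting. Expected shares changed as well, such as from 28.9% to 19.1% for Hox and from 36.7% to 40.8% for dopaminergic genes. These effects were not separated. Lost there were midbrain patterning (11.1% marked), H3K36 methylation (75%) and, each with 0% marked, dopaminergic, microglia, endothelium, meninges, forebrain, liver, muscle, germline and Hox. With a −log10 q of at least 2, midbrain patterning (14.8%), dopaminergic (7.14%), cell cycle (66.7%) and microglia (6.67%) were lost. At 25% covered, cell cycle (50%) and muscle (0%) were lost and protocadherins gained (31.6%). Microglia was also lost with the pooled list and at 5% covered (13.3%). Serotonergic genes (0%) were gained at 5% covered and axon guidance (9.52%) with Fisher's exact test. With single replicates' lists the percent marked ran from 62.5 to 79.2 for cell cycle (lost without replicate 1), 7.14 to 21.4 for oligodendrocyte lineage (gained without replicate 1), 6.67 for microglia and 7.14 for endothelium (both lost without replicate 1). Over all settings, the 17 lists with a call kept it in 130 results and lost it in 22. The 12 lists without a call gained one in 4 results, and in 10 they moved from below to above the expected share with no call. These were GABAergic with the pooled list and at 5% covered (both 46.2%) and without replicate 2 (38.5%; 23.1% and still below without replicate 1), axon guidance with the pooled list (19.0%), at 5% covered (33.3%) and in genes overlapping no other (20%), radial glia with the pooled list and at 5% covered (both 34.8%), and imprinted genes at 25% covered (27.3%) and without replicate 1 (31.8%; also 31.8% but still below without replicate 2).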

Other observations

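The comparisons in this part were chosen after the strongest peaks had been seen, so they describe the data. Zinc finger genes of the Zfp family held 7 of the 10 strongest replicated peaks, 18 of the 50 strongest and 27 of the 100 strongest, against 1.90% of all 113504. The strongest peak in each of 241 marked Zfp genes had a median signal value of 6.97, against 6.27 in 7358 other marked genes. The medians were 7.07 and 6.34 in replicate 1 and 6.59 and 6.09 in replicate 2. A two-sided permutation test of these differences gave p = 0.0001 for the replicated list and for replicate 1, the smallest that 10000 permutations can give, and 0.0006 for replicate 2. It was made on the family picked for its strong peaks and is no independent evidence.

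The last exon, which in many of these genes encodes the zinc fingers, had a higher covered share than the rest of the gene. In 230 marked Zfp genes with more than 2 exons, it was 73.3% covered against 35.8% for the rest of the gene, and was the higher in 205 of them (89.1%). In 7191 other marked genes the last exon was 66.7% covered and the rest 40.6%, with the last exon higher in 77.1%. The ratio of last exon to rest was 2.02 for Zfp genes and 1.61 for others in replicate 1, and 2.22 and 1.70 in replicate 2. The difference between the gene groups was not tested, and the last exons of Zfp genes were longer (median 2672 against 1313 bp). Last exons lie at the 3′ end, towards which cover rose along genes, so exon and position were not separated.

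The little cover outside protein-coding genes mostly followed their 3′ ends. Of the 5.19 Mb outside gene bodies, 83.9% lay within 5 kb past the annotated end of a protein-coding gene and 12.9% within 5 kb before a start, and base pairs near both count for each. The percents were 81.5 and 12.7 in replicate 1, and 83.0 and 12.9 in replicate 2.

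The 5 widest replicated peaks, chosen after their values were seen, were 25.7 kb in Prrc2b, 23.4 kb in Ubr4, 23.2 kb in the spectrin gene Sptan1, 22.8 kb in the polarity gene Scrib and 21.3 kb in the histone methyltransferase gene Kmt2a.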
